A study of Mus musculus with 12 samples.

How the data were processed

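RNA from the cortex of mouse embryos at day E15.5 was sequenced in 12 libraries, 4 each from a conditional knockout (cKO) labelled BAF155, a conditional knockout labelled Pax6 and a control. The labels give the strain as C57BL/6J. Per the labels' protocols, total RNA was isolated with the RNeasy kit and libraries were made with the TruSeq RNA v2 kit, which does not mark strand. Reads from a gene and from an antisense partner that overlaps its exons can therefore not be told apart in these counts. Among the genes named below, exons of other genes overlap Smarcc1, Nphs1, Hs3st3a1, Ltbp2, Ly6g6e, Nmbr, Dlx6os1, Serpinb2, Veph1, Prss41, Tagap, Pla2g4b, Eif3j2, Eomes, Tnc, Sdc3, Ebf3, Trp73, Hs3st4, Dlx1, Wnt5a, Sfrp2, Notch2, Notch3, Plk1, Smarca2, Smarca4, Bcl11a, Bcl7a, Fn1, Prox1, Penk and Ppp1r1b. Reads of the paralogs Hbb-bs and Hbb-bt, Eif3j2 and Eif3j1, and of Rpl29 and its pseudogenes are hard to assign. Groups and replicate numbers 1 to 4 were taken from the sample titles. Nothing in the labels says whether the 4 libraries of a group came from separate embryos, so the p-values measure the spread between these libraries, which may be technical. The 4 controls cannot all come from the same embryo, since replicates 1 and 2 differed in sex from 3 and 4.

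The values used were the raw read counts per gene that the authors deposited, whole numbers with no normalization and no header line, 1 file per library. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program and the gene annotation behind the counts are not given in the sources used here. Each file listed 48709 Ensembl gene identifiers, of which 48349 matched GENCODE M21, used here for symbols, coordinates, gene type, length and GC content. The other 360 identifiers held at most 0.0397% of the reads of a library. Total counts ran from 15.2 to 32.05 M reads per library, and no row without a gene was present.

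Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 16511, and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion and 1 coefficient per group was fitted to all 12 libraries. The contrasts were BAF155 cKO minus control, Pax6 cKO minus control and BAF155 cKO minus Pax6 cKO. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 from edgeR's quasi-likelihood F-test, and every adjusted p for a gene comes from that test. The standard error of a log2 fold change is its absolute value divided by the square root of F. CPM values are counts per M of TMM-scaled library size, given as mean ± SD over n = 4 libraries.

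Gene lists for 26 cell types, pathways and complexes were fixed before the data were examined, with the comparisons, the tests and the other settings to be tried. Each list was tested against the other genes with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, adjusted over the 26 lists of a contrast. Beside it stand camera with an estimated correlation and fry. The count "adjusted over the list alone" uses p-values adjusted within the members of that list. The lists hold genes named in the literature for the embryonic forebrain and some genes stand in more than 1 list.

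The genes named were set by a rule fixed before the data were examined. They are the targeted genes Smarcc1 and Pax6 with Smarcc2, the 10 highest and 10 lowest called genes by log2 fold change per comparison with control, and 5 of each for the direct contrast and for calls shared by both cKOs. Ranked genes had to have all 4 libraries of a group on one side of the other group's 4, a separation that chance gives for 2.86% of genes, and a mean of at least 1 CPM in at least 1 group. Genes without a symbol, predicted models and 6 sex-linked genes were left out of the ranking. Per list and comparison the rule adds the 2 called members of smallest adjusted p in each direction, or the 2 of highest CPM where none was called. It also fixes Eomes, Neurog2, Insm1, Tfap2c, Cdh1, Cdh2, Cdc42ep4, Foxn4 and Gsx2. Some genes that the rule names are not reported here. Cdh1 did not pass the filter on low counts and has no value. A gene named outside this rule is said to have been chosen after its values were seen.

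Other settings, also fixed before the data were examined, were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 4 libraries, a fit of only the 8 libraries compared, the replicate number as a block, a fold threshold of 1.2, a correction of each library's trend on GC content and gene length (loess, span 0.3), the BAF155 cKO libraries of each sequencing lane alone, and leaving out each of the 12 libraries. GC content and length were known for 99.7% of the tested genes. Lane numbers came from the names of the deposited count files: all controls were in lane 8, all Pax6 cKO libraries and BAF155 cKO replicates 1 and 2 in lane 1, and BAF155 cKO replicates 3 and 4 in lane 3. Lane 8 held controls alone, so lane and group cannot be told apart in the comparisons with control.

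Xist and Y-linked genes divided the libraries by sex in a way that crosses the groups, as given with the results. After this had been seen, fits were added with controls of the same sex only, with controls of the other sex only, with controls of the same sex together with the GC and length correction, and with Pax6 cKO replicates 1 and 3 only. In the same-sex fit the BAF155 cKO was set against control replicates 3 and 4 and the Pax6 cKO against control replicates 1 and 2. Its direct contrast is the difference of these effects.

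No library pair within a group agreed to within sampling noise. The chi-square per gene was 5.95 to 42.8 between controls, 10.7 to 51 between BAF155 cKO libraries and 3.15 to 20.5 between Pax6 cKO libraries, where sampling noise alone gives 1, so all 12 libraries were kept.

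The scripts were tested on simulated counts for the 16511 genes with 200 genes changed in the BAF155 cKO against control. The fit recovered 70.1% of genes changed 1.5-fold, 94% of those changed 2-fold and 98.5% of those changed 4-fold, with 8 unchanged genes called, and called 0 genes in the Pax6 cKO, which was simulated without a change. On the same simulation DESeq2 recovered 94% and voom 91% of genes changed 2-fold. Camera found the 1 shifted list (adjusted p 6.08e-41) and 0 others. Genes were simulated independently of each other, so this does not test the preset correlation where the members of a list vary together. A GC trend added to the BAF155 cKO gave 3062 calls without the correction and 0 with it. Effects shared by both comparisons were set beside 20 simulations of unchanged groups against the same controls and beside fits with the 4 controls divided between the cKOs.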

Results

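Counts of reads per gene were available for 12 libraries from the cortex of mouse embryos at day E15.5, 4 from a BAF155 conditional knockout (cKO), 4 labelled Pax6 cKO and 4 from control. BAF155 is the protein of the gene Smarcc1 and a core subunit of the BAF chromatin remodelling complex. Pax6 encodes a transcription factor of radial glia, the stem cells of the cortex. Total counts were 25.4, 28.3, 15.8 and 15.2 M reads in BAF155 cKO replicates 1 to 4, 30.3, 21.4, 21.8 and 21.8 M reads in control replicates 1 to 4, and 27.5, 24.6, 32.05 and 22.8 M reads in replicates 1 to 4 labelled Pax6 cKO. After the filter on low counts, 16511 genes were tested.

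Smarcc1 (ENSMUSG00000032481, mm10 chromosome 9, 110117708 to 110240178, plus strand) was lowest in the BAF155 cKO. It was measured at 303 ± 68.7 CPM in control, 127 ± 10.8 CPM in the BAF155 cKO and 186 ± 6.71 CPM in the libraries labelled Pax6 cKO (mean ± SD, n = 4 each). The log2 fold change against control was −1.25 (SE 0.13, adjusted p = 1.64e-05) in the BAF155 cKO and −0.71 (SE 0.13, adjusted p = 0.00128) in the libraries labelled Pax6 cKO. For same-sex controls alone these were −1.50 and −0.41. Exons of Dhx30 on the other strand overlap Smarcc1, and these counts do not mark strand. Its paralog Smarcc2, which encodes BAF170, had a log2 fold change of −0.20 (SE 0.11, adjusted p = 0.2) in the BAF155 cKO and −0.41 (SE 0.11, adjusted p = 0.00923) in the libraries labelled Pax6 cKO, the latter not called against the 2 controls of the same sex (adjusted p = 0.128).

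Counts of Pax6 (ENSMUSG00000027168, mm10 chromosome 2, 105668900 to 105697364, plus strand) went against the label. They were 110.2 ± 19.1 CPM in control, 314 ± 40.3 CPM in the BAF155 cKO and 389 ± 8.73 CPM in the libraries labelled Pax6 cKO, where each of the 4 libraries lay above each control. The log2 fold change was 1.51 (SE 0.12, adjusted p = 9.98e-07) in the BAF155 cKO and 1.82 (SE 0.12, adjusted p = 9.46e-08) in the libraries labelled Pax6 cKO. With same-sex controls alone these were 1.38 and 1.96. Whole-gene counts may include reads from parts of a gene outside the deleted part, so they do not measure how much intact transcript was left. The long noncoding RNA Paupar, transcribed next to Pax6, rose by a log2 fold change of 2.95 and 3.15 in the same order.

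**Figure D1:**
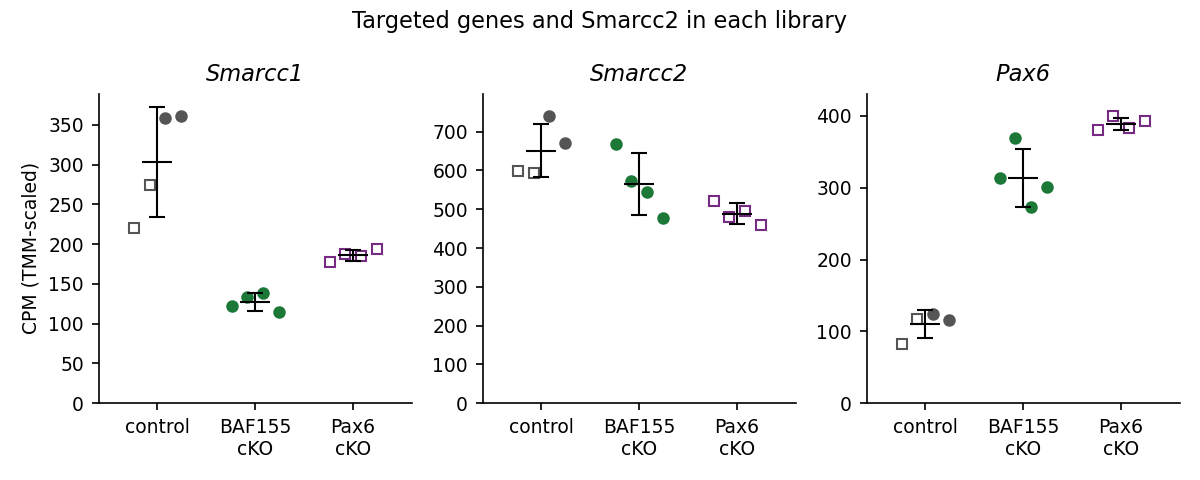
CPM (TMM-scaled) of Smarcc1, Smarcc2 and Pax6 in each of the 12 libraries by group, with the mean as a horizontal line and bars of ± SD (n = 4). Filled circles are libraries with Xist above 100 CPM and open squares the others; Pax6 lies between 273 and 399 CPM in the cKO libraries and between 82.0 and 125 CPM in control.

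The groups also differed in sex. Xist, expressed from the inactive X chromosome of females, was measured at 1811 to 3115 CPM in the 4 BAF155 cKO libraries, 964 CPM in control replicates 3 and 4 and at most 5.75 CPM in the other 6. Summed Y-linked genes reached 293 to 399.9 CPM in control replicates 1 and 2 and the libraries labelled Pax6 cKO, and at most 1.11 CPM elsewhere. Each comparison with control was therefore also made against the 2 controls of the same sex, an alternative chosen after the data had been seen. The share of mitochondrial reads was 1.57% to 3.27% in the BAF155 cKO, 1.21% to 2.27% in control and 2.04% to 2.92% in the libraries labelled Pax6 cKO. It was 2.92% and 3.27% in BAF155 cKO replicates 1 and 4 and 1.57% and 2.09% in 2 and 3. Xist was at 3115 and 3083 CPM against 1997 and 1811 CPM in the same order. The chi-square per gene was 14 between replicates 1 and 4, 10.7 between 2 and 3 and 20.6 to 51 between the other pairs. Some libraries of other groups lay closer than these other pairs. BAF155 cKO replicate 2 gave 21.6 with control replicate 4, against 51 and 45.6 with BAF155 cKO replicates 1 and 4. BAF155 cKO replicate 4 gave 16.1 with replicate 1 labelled Pax6 cKO. The closest library to each BAF155 cKO replicate was still in the same group.

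The comparison of the BAF155 cKO with control, named in the series design, asks which genes differ in expression in the cKO cortex. By camera, lists of radial glia (12 of 22 genes lower), basal intermediate progenitors (8 of 22) and upper-layer neurons (11 of 14) fell, and lists of Cajal-Retzius and preplate neurons (9 of 12 higher) and of the ventral telencephalon (14 of 24) rose. With an estimated correlation the radial glia and upper-layer lists were called (adjusted p = 0.0233 each) and the other 10 called lists were not. This test called 0 lists against the 2 controls of the same sex (lowest adjusted p = 0.0864). Fry called 11 lists with all 4 controls, without the BAF complex list (fry adjusted p = 0.107). Eomes, a transcription factor of basal intermediate progenitors, fell from 247 ± 56.6 CPM in control to 63.8 ± 17.2 CPM (SD, n = 4 each), a log2 fold change of −1.95 (SE 0.18, adjusted p = 3.8e-06). Dlx1, a homeobox gene of the ventral telencephalon, rose from 245 ± 39.3 to 502 ± 25.5 CPM, a log2 fold change of 1.03 (SE 0.10, adjusted p = 9.77e-06). Of the genes tested, 998 were higher and 1248 lower, of which 197 and 222 by at least 2-fold. Against the 2 controls of the same sex, 2085 were higher and 2449 lower, and 797 and 1101 of these were also called with all 4 controls.

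Among the highest called genes, in rank order, were Alb, Prdm13, Kirrel2, Sim1, Otp, Nphs1, Apoa1, Uncx and Arid3c. Prdm13, a transcription factor of the PR domain family, rose from 0.193 ± 0.111 to 10.7 ± 3.94 CPM, a log2 fold change of 5.83 (SE 0.34, adjusted p = 2.2e-08). The log2 fold change was 5.59 for Kirrel2 and 5.18 for Nphs1, which encodes nephrin, 5.44 for Sim1, a transcription factor of the hypothalamus, 3.90 for the homeobox gene Uncx and 3.75 for Arid3c. Otp, also a transcription factor of the hypothalamus, was measured at 1.14 ± 0.786 CPM against 0.024 ± 0.0278 CPM. Alb and Apoa1 are abundant liver transcripts. Alb, which encodes albumin, was at 0.621, 1.11, 25.9 and 156.5 CPM in BAF155 cKO replicates 1 to 4 and at most 0.0967 CPM in control. Apoa1 rose by a log2 fold change of 4.09. The calls of Alb (not called without control 1, 2, 3 or 4, adjusted p = 0.055 to 0.0922) and Apoa1 (not called without control 3 or 4, adjusted p = 0.0734 to 0.0764) were each lost without 1 library. These calls and that of Otp were also lost against the 2 controls of the same sex, with adjusted p of 0.0627 to 0.0796.

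The 10 lowest called genes were Slc14a1 (−4.86), Rlbp1 (−3.80), Tac2 (−3.65), Neurod4 (−3.25), Hs3st3a1 (−3.09), Pdlim3 (−2.99), Dapp1 (−2.97), Dmrta1 (−2.90), Ltbp2 (−2.87) and Ly6g6e (−2.72). A single value in brackets after a gene is its log2 fold change. Rlbp1, a retinaldehyde-binding protein, fell from 146 ± 11.3 to 10.4 ± 1.17 CPM (SE of the log2 fold change 0.10, adjusted p = 1.91e-12). Slc14a1 encodes a urea transporter, Tac2 a tachykinin precursor and Neurod4 a proneural transcription factor.

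Of the 22 radial glia genes measured, 12 fell, 0 rose and 10 did not pass the test. For radial glia genes, the count was 13 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.29e-16, adjusted p = 0.0233 with an estimated correlation). Aldoc (−2.24) and Veph1 (−2.57) had the smallest adjusted p. Among 22 genes of basal intermediate progenitors, 8 fell, 1 rose and 13 did not pass the test. For basal intermediate progenitors, the count was 10 lower and 2 higher adjusted over the list alone (camera adjusted p = 2.67e-06, adjusted p = 0.327 with an estimated correlation). Besides Eomes and Tac2 the proneural gene Neurog2 fell by 1.94 on the log2 scale and Neurog1 by 1.82, while Dll3, a Notch ligand, rose (0.85). Insm1 did not pass the test (log2 fold change −0.33, adjusted p = 0.15). Among 16 basal radial glia genes, 4 fell, 2 rose and 10 did not pass the test. For basal radial glia, the count was 9 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00696, adjusted p = 0.0687 with an estimated correlation). Tnc (−1.53) and Sdc3 (−0.49) fell, and Foxn4 (1.84) and Pth2r (0.99) rose. In the list of 12 Pax6-dependent cortical genes, 6 fell, 0 rose and 6 did not pass the test. For Pax6-dependent cortical genes, the count was 8 lower and 0 higher adjusted over the list alone (camera adjusted p = 1.19e-08, adjusted p = 0.16 with an estimated correlation). Among them Tfap2c fell by 1.26 on the log2 scale and Sfrp2 by 0.65, while Fabp7 had 0.09 (adjusted p = 0.632).

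Of 14 upper-layer genes, 11 fell, 0 rose and 3 did not pass the test. For upper-layer neurons, the count was 11 lower and 0 higher adjusted over the list alone (camera adjusted p = 1.45e-17, adjusted p = 0.0233 with an estimated correlation). Unc5d fell from 144 ± 5.51 to 51.9 ± 6.43 CPM (−1.47), and Pou3f2 fell too (−1.27). For the 14 deep-layer genes, 4 fell, 0 rose and 10 did not pass the test. For deep-layer neurons, the count was 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00935, adjusted p = 0.467 with an estimated correlation). Hs3st4 (−0.89), Tle4 (−0.58) and Tbr1 (−0.56) fell, the last (not called without BAF155 cKO 1, 3 or 4 or control 3 or 4, adjusted p = 0.0658 to 0.166). In the pan-neuronal list of 18, 4 fell, 0 rose and 14 did not pass the test. For pan-neuronal genes, the count was 4 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.00237, adjusted p = 0.377 with an estimated correlation). Rbfox1 (−0.80), Cntn2 (−0.85) and Neurod2 (−0.64) fell. In the list of 12 Cajal-Retzius and preplate genes, 1 fell, 9 rose and 2 did not pass the test. For Cajal-Retzius and preplate genes, the count was 1 lower and 9 higher adjusted over the list alone (camera adjusted p = 1.18e-06, adjusted p = 0.0687 with an estimated correlation). Ebf3 (0.97), Trp73 (0.83) and Calb2 (0.27) rose, the last (not called without BAF155 cKO 3 or 4 or control 2 or 3, adjusted p = 0.0527 to 0.0854), and Spock1 fell (−0.51). Of 24 genes of the ventral telencephalon and GABAergic neurons, 0 fell, 14 rose and 10 did not pass the test. For ventral and GABAergic genes, the count was 0 lower and 16 higher adjusted over the list alone (camera adjusted p = 3.67e-12, adjusted p = 0.162 with an estimated correlation). Besides Dlx1, the receptor gene Erbb4 rose (1.05), as did the ventral progenitor gene Gsx2 (1.06). In the striatal list of 12, 1 fell, 1 rose and 10 did not pass the test. For striatal neurons, the count was 1 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.999). Penk rose (1.15) (not called without BAF155 cKO 3 or 4 or control 1, 3 or 4, adjusted p = 0.0913 to 0.157) and Ppp1r1b fell (−0.89).

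Of 35 genes of adherens junctions and apical polarity, 12 fell, 1 rose and 22 did not pass the test. For junction and polarity genes, the count was 18 lower and 1 higher adjusted over the list alone (camera adjusted p = 4.73e-08, adjusted p = 0.334 with an estimated correlation). Cdh4 (−0.66), Ctnnd2 (−0.82), Celsr1 (−1.07), Cdh2, which encodes N-cadherin (−0.49), and Cdc42ep4 (−0.58) fell, and Crb1 rose (1.02). For Wnt signalling and the cortical hem, of 26 genes, 8 fell, 2 rose and 16 did not pass the test. For Wnt and hem genes, the count was 9 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0763). Wnt5a (0.96) and Wif1 (1.47) rose, and Dkk3 (−1.34), Bmp7 (−1.01) and Sfrp1 (−0.62) fell. Of 17 genes of Notch signalling, 3 fell, 1 rose and 13 did not pass the test. For Notch signalling, the count was 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.148). Rbpj fell (−0.45) (not called without BAF155 cKO 1 or 4 or control 3 or 4, adjusted p = 0.0626 to 0.0865). For the other 28 genes of the BAF complex, 3 fell, 0 rose and 25 did not pass the test. For BAF complex, the count was 3 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.0342, adjusted p = 0.74 with an estimated correlation). Smarca2 (−0.47) and Bcl11a (−0.44) (not called without BAF155 cKO 4, adjusted p = 0.0501) fell. Against the 2 controls of the same sex the Wnt (camera adjusted p = 0.00479) and Notch (0.00435) lists were also called, but not with an estimated correlation (adjusted p = 0.545 and 0.439).

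Of 24 genes of DNA replication, 0 fell, 3 rose and 21 did not pass the test. For DNA replication, the count was 0 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.881). Prim1 (0.57) and Rfc3 (0.47) rose. Of 24 genes of mitosis, 0 fell, 2 rose and 22 did not pass the test. For mitosis, the count was 0 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.881). Cenpa (0.47) and Birc5 (0.44) rose, and against the 2 controls of the same sex the list was called lower (camera adjusted p = 0.0225, adjusted p = 0.787 with an estimated correlation). Among 20 targets of p53, 0 fell, 1 rose and 19 did not pass the test. For p53 targets, the count was 2 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.999). Psrc1 rose (0.38) (not called without BAF155 cKO 1 or 4 or control 1, 2 or 4, adjusted p = 0.0663 to 0.135). For 14 immediate early and stress genes, 0 fell, 0 rose and 14 did not pass the test. For immediate early genes, the count was 0 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.304). Of 8 genes of oligodendrocyte precursors, 2 fell, 2 rose and 4 did not pass the test. For oligodendrocyte precursors, the count was 2 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.969). Olig2 rose (0.94) and Sox10 fell (−1.11). In the thalamus list of 8, 1 fell, 2 rose and 5 did not pass the test. For thalamus, the count was 1 lower and 5 higher adjusted over the list alone (camera adjusted p = 0.0763). Lhx9 (0.95) and Prox1 (0.54) rose and Tcf7l2 fell (−0.86).

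Among the lists of other cell types, the erythroid list was called. Of 12 microglia genes, 1 fell, 0 rose and 11 did not pass the test. For microglia, the count was 2 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.304). Cx3cr1 fell (−0.65) (not called without BAF155 cKO 1 or 2 or control 2, 3 or 4, adjusted p = 0.0525 to 0.0962). For 12 endothelial genes, 0 fell, 0 rose and 12 did not pass the test. For endothelial cells, the count was 0 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.924). Of 10 pericyte genes, 0 fell, 0 rose and 10 did not pass the test. For pericytes, the count was 0 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.881). Of 11 genes of meninges and fibroblasts, 1 fell, 1 rose and 9 did not pass the test. For meningeal genes, the count was 1 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.881). Dcn rose (1.09) and Cxcl12 fell (−1.26). For 9 choroid plexus genes, 0 fell, 0 rose and 9 did not pass the test. For choroid plexus, the count was 0 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.999). In the erythroid list of 10, 0 fell, 2 rose and 8 did not pass the test. For erythroid cells, the count was 0 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.0063, adjusted p = 0.385 with an estimated correlation). Hbb-bt (0.67) (not called without control 3, adjusted p = 0.0559) and Tfrc (0.37) rose. The erythroid list was not called against the 2 controls of the same sex (camera adjusted p = 0.0773), nor were the genes Psrc1, Calb2 and Cx3cr1 (adjusted p = 0.159, 0.0677 and 0.0926). Median, mean and camera direction differed in sign for the striatal list (median 0.16, mean 0.12, test lower), the meninges list (0.05, 0.07, lower), the choroid plexus list (0.06, −0.06, lower) and the DNA replication list (−0.05, −0.04, higher).

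The count of genes called in the BAF155 cKO moved by over 1.5 times without BAF155 cKO replicate 1 (515 higher, 809 lower), 2 (1973 and 2100) or 4 (346 and 655) and without control replicate 3 (413 and 751) or 4 (496 and 791). All controls were sequenced in lane 8 and the BAF155 cKO in lanes 1 and 3, so lane and group cannot be told apart.

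**Figure D2:**
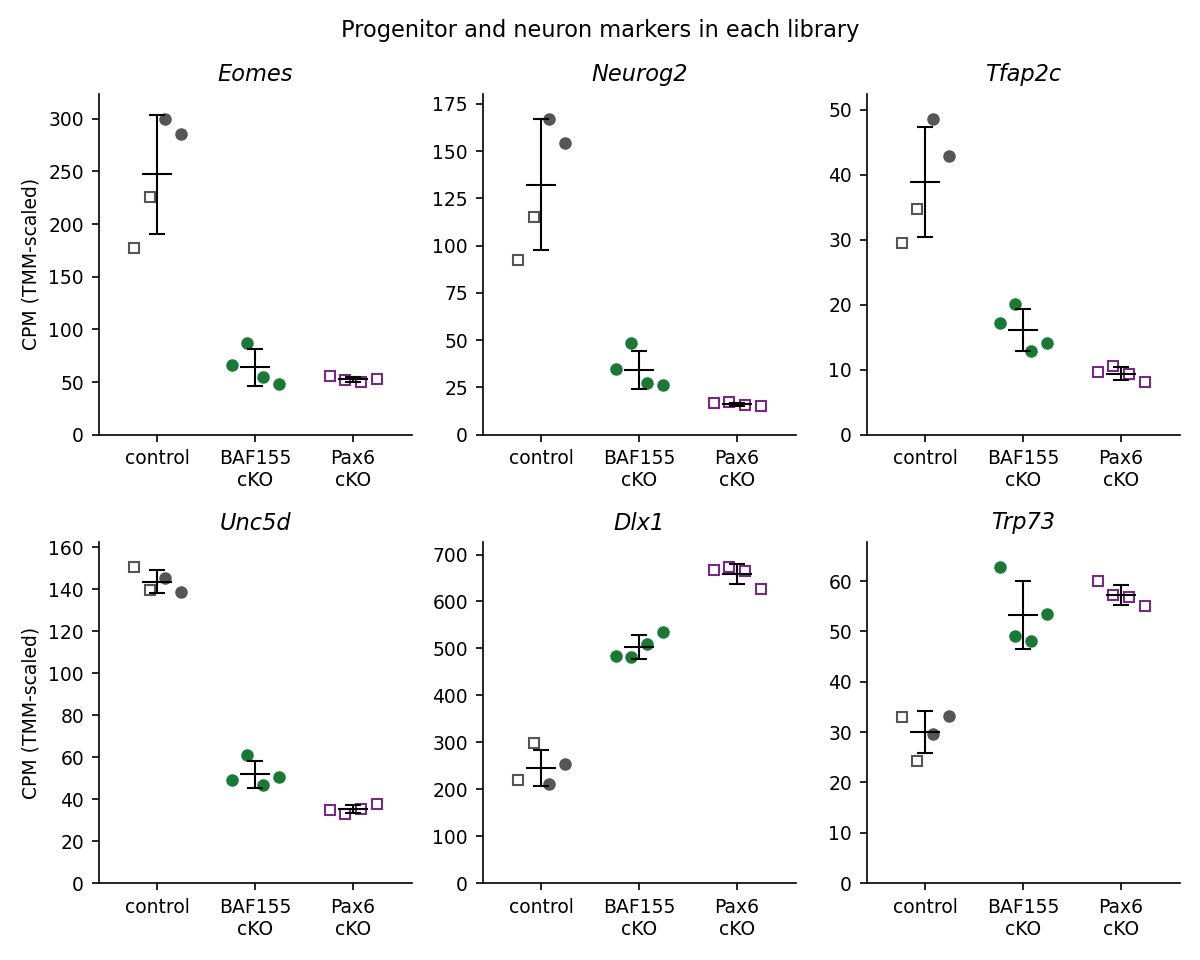
CPM (TMM-scaled) of Eomes, Neurog2, Tfap2c, Unc5d, Dlx1 and Trp73 in each of the 12 libraries by group, with the mean as a horizontal line and bars of ± SD (n = 4); filled circles are libraries with Xist above 100 CPM and open squares the others. Mean Eomes was 247 CPM in control, 63.8 in the BAF155 cKO and 52.7 in the libraries labelled Pax6 cKO.

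The comparison of the libraries labelled Pax6 cKO with control, also named in the series design, asks the same of the Pax6 cKO. By camera, lists of radial glia (16 of 22 genes lower), basal intermediate progenitors (15 of 22), upper-layer neurons (11 of 14) and adherens junctions (24 of 35) fell, and lists of Cajal-Retzius and preplate neurons (10 of 12 higher) and of the ventral telencephalon (16 of 24) rose. With an estimated correlation 0 of the 12 called lists were called (lowest adjusted p = 0.0772), but against the 2 controls of the same sex the lists of upper-layer neurons and of Cajal-Retzius and preplate neurons were (adjusted p = 0.0349 each). Fry called 14 lists with all 4 controls, among them p53 targets and choroid plexus (fry adjusted p = 0.0116 and 0.021). Against the 2 controls of the same sex fry did not call these 2 (0.0823 and 0.0842). Neurog2 fell from 132 ± 34.5 CPM in control to 16 ± 0.959 CPM (SD, n = 4 each), a log2 fold change of −3.04 (SE 0.21, adjusted p = 1.08e-07). Eomes fell to 52.7 ± 2.24 CPM, a log2 fold change of −2.23 (SE 0.18, adjusted p = 6.31e-07), and Dlx1 rose to 658 ± 20.9 CPM, a log2 fold change of 1.42 (SE 0.10, adjusted p = 2.29e-07). Of the genes tested, 2745 were higher and 3121 lower, of which 290 and 277 by at least 2-fold. Against the 2 controls of the same sex, 744 were higher and 1028 lower, and 710 and 1002 of these were also called with all 4 controls. In that fit 12 radial glia, 11 basal intermediate progenitor, 11 upper-layer and 11 junction genes were lower in the libraries labelled Pax6 cKO. Higher were 9 Cajal-Retzius and preplate genes and 12 ventral genes. In the BAF155 cKO against its 2 controls of the same sex, these counts were 16, 12, 11 and 24 lower and 7 and 12 higher. That fit called 27.5% of all tested genes, against 10.7% in the libraries labelled Pax6 cKO.

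The 10 highest called genes were Arid3c (4.35), Prdm13 (3.65), Paupar (3.15), Nmbr (2.76), Kirrel2 (2.63), Wls (2.29), Dlx6os1 (2.18), Synpr (2.07), Serpinb2 (2.02) and Frmd7 (2.02). Wls, which is needed for the secretion of Wnt proteins, rose from 31.9 ± 5.03 to 156 ± 13.9 CPM (SE 0.12, adjusted p = 3.59e-09). Nmbr encodes the receptor of neuromedin B and Synpr the synaptic vesicle protein synaptoporin. The 10 lowest were Slc14a1 (−5.77), Neurog1 (−4.57), Neurod4 (−4.35), Dmrta1 (−3.62), Rlbp1 (−3.55), Veph1 (−3.20), Neurog2 (−3.04), Ly6g6e (−3.01), Pdlim3 (−3.01) and Dapp1 (−2.65). Rlbp1 fell to 12.4 ± 0.88 CPM (SE 0.10, adjusted p = 3.69e-12). Dlx6os1 stands under 2 identifiers.

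Of the 22 radial glia genes, 16 fell, 1 rose and 5 did not pass the test. For radial glia genes, the count was 16 lower and 2 higher adjusted over the list alone (camera adjusted p = 5.94e-11, adjusted p = 0.0842 with an estimated correlation). Aldoc fell (−1.71) and Fabp7 rose (0.48). Among the 22 genes of basal intermediate progenitors, 15 fell, 2 rose and 5 did not pass the test. For basal intermediate progenitors, the count was 15 lower and 3 higher adjusted over the list alone (camera adjusted p = 5.94e-11, adjusted p = 0.131 with an estimated correlation). The glutamate transporter gene Slc17a6 (−1.23) and Insm1 (−0.45) fell, the latter (not called without control 2, 3 or 4 or library 1, 2, 3 or 4 labelled Pax6 cKO, adjusted p = 0.0533 to 0.119), and Dll3 rose (0.51). Of 16 basal radial glia genes, 6 fell, 3 rose and 7 did not pass the test. For basal radial glia, the count was 6 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.0868 with an estimated correlation). Tnc (−1.41) and Sdc3 (−0.88) fell and Pth2r rose (1.13), while Foxn4 had 0.55 (adjusted p = 0.254). In the list of Pax6-dependent cortical genes, of 12 measured, 10 fell, 1 rose and 1 did not pass the test. For Pax6-dependent cortical genes, the count was 10 lower and 2 higher adjusted over the list alone (camera adjusted p = 2.48e-11, adjusted p = 0.0868 with an estimated correlation). Tfap2c fell by 2.05 on the log2 scale and Sfrp2 by 1.40.

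For the 14 upper-layer genes, 11 fell, 0 rose and 3 did not pass the test. For upper-layer neurons, the count was 12 lower and 0 higher adjusted over the list alone (camera adjusted p = 3.31e-15, adjusted p = 0.0772 with an estimated correlation). Unc5d (−2.02) and Pou3f2 (−1.07) fell. Of 14 deep-layer genes, 8 fell, 2 rose and 4 did not pass the test. For deep-layer neurons, the count was 8 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.0706). Tbr1 (−1.26), Tle4 (−0.48) and Hs3st4 (−0.60) fell and Crym rose (1.04). Of 18 pan-neuronal genes, 7 fell, 1 rose and 10 did not pass the test. For pan-neuronal genes, the count was 8 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.0232, adjusted p = 0.503 with an estimated correlation). Neurod2 (−1.11), Cntn2 (−1.15) and Rbfox1 (−0.84) fell, and Stmn2 rose (0.42) (not called without control 3 or 4 or library 2 or 4 labelled Pax6 cKO, adjusted p = 0.0507 to 0.0768). Of 12 Cajal-Retzius and preplate genes, 1 fell, 10 rose and 1 did not pass the test. For Cajal-Retzius and preplate genes, the count was 1 lower and 10 higher adjusted over the list alone (camera adjusted p = 4.19e-07, adjusted p = 0.0842 with an estimated correlation). Calb2 (0.86), Trp73 (0.93) and Ebf3 (0.46) rose and Spock1 fell (−0.55). Among 24 genes of the ventral telencephalon and GABAergic neurons, 0 fell, 16 rose and 8 did not pass the test. For ventral and GABAergic genes, the count was 1 lower and 16 higher adjusted over the list alone (camera adjusted p = 1.63e-11, adjusted p = 0.149 with an estimated correlation). Erbb4 (1.09) and Gsx2 (1.06) rose. Of 12 striatal genes, 1 fell, 0 rose and 11 did not pass the test. For striatal neurons, the count was 1 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.493). Ppp1r1b fell (−0.97).

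Among 35 genes of adherens junctions and apical polarity, 24 fell, 2 rose and 9 did not pass the test. For junction and polarity genes, the count was 26 lower and 2 higher adjusted over the list alone (camera adjusted p = 2.48e-11, adjusted p = 0.188 with an estimated correlation). Celsr1 (−2.14), Cdh4 (−1.61), Ctnnd2 (−0.76), Cdc42ep4 (−0.60) and Cdh2 (−0.59) fell and Crb1 rose (0.86). Of 26 genes of Wnt signalling and the cortical hem, 12 fell, 2 rose and 12 did not pass the test. For Wnt and hem genes, the count was 12 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.000744, adjusted p = 0.503 with an estimated correlation). Sfrp1 (−0.89), Dkk3 (−0.79) and Bmp7 (−0.65) fell, and Wif1 (1.66) and Wnt5a (0.42) rose. For Notch signalling, of 17 genes, 11 fell, 1 rose and 5 did not pass the test. For Notch signalling, the count was 11 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000776, adjusted p = 0.503 with an estimated correlation). The receptor genes Notch2 (−0.88) and Notch3 (−0.98) and Rbpj (−0.48) fell. Of 28 other genes of the BAF complex, 12 fell, 0 rose and 16 did not pass the test. For BAF complex, the count was 14 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00421, adjusted p = 0.503 with an estimated correlation). Bcl7a (−0.56), the ATPase genes Smarca4 (−0.76) and Smarca2 (−0.26) and Bcl11a (−0.35) fell, Smarca2 (not called without library 1 or 3 labelled Pax6 cKO, adjusted p = 0.0518 to 0.0594) and Bcl11a (not called without control 3 or 4 or library 3 labelled Pax6 cKO, adjusted p = 0.0535 to 0.0747). Against the 2 controls of the same sex the list was not called (camera adjusted p = 0.0519). There 2 genes of the BAF complex and 4 of Notch signalling fell, against 11 and 10 in the BAF155 cKO with its controls of the same sex. Of all tested genes these fits called 10.7% and 27.5%. The median log2 fold changes were −0.12 and −0.28, against −0.24 and −0.37 in the BAF155 cKO. The direct contrast with these controls called 0 genes of either list (camera adjusted p = 0.0132 and 0.346, and 0.634 and 0.876 with an estimated correlation).

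For DNA replication, of 24 genes, 4 fell, 6 rose and 14 did not pass the test. For DNA replication, the count was 4 lower and 7 higher adjusted over the list alone (camera adjusted p = 0.349). Prim1 (0.78) and Rfc3 (0.62) rose and Mcm3 fell (−0.76). For mitosis, of 24 genes, 3 fell, 3 rose and 18 did not pass the test. For mitosis, the count was 3 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.835). Cenpa (0.69) and Birc5 (0.57) rose, and Mki67 (−0.71) and Plk1 (−0.75) (not called without control 3, adjusted p = 0.0616) fell. Against the 2 controls of the same sex both lists were called higher (camera adjusted p = 0.00286 and 0.00936), but not with an estimated correlation (adjusted p = 0.505 and 0.657) or by fry (0.112 and 0.26). There Mcm3, Mki67 and Plk1 were not called (adjusted p = 0.233, 0.17 and 0.299). Of 20 p53 targets, 1 fell, 4 rose and 15 did not pass the test. For p53 targets, the count was 1 lower and 4 higher adjusted over the list alone (camera adjusted p = 0.472). Eda2r (1.06) and Psrc1 (0.63) rose. For the 14 immediate early and stress genes, 2 fell, 2 rose and 10 did not pass the test. For immediate early genes, the count was 2 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.504). Btg1 rose (0.71). Among 8 genes of oligodendrocyte precursors, 1 fell, 2 rose and 5 did not pass the test. For oligodendrocyte precursors, the count was 1 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.867). Olig2 rose (0.72). For the 8 thalamus genes, 2 fell, 2 rose and 4 did not pass the test. For thalamus, the count was 2 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.807). Prox1 rose (0.54) and Tcf7l2 fell (−1.17).

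Transcripts of the choroid plexus differed between the libraries labelled Pax6 cKO. Ttr, an abundant choroid plexus transcript, was at 12.9, 318, 91.2 and 193 CPM in replicates 1 to 4 and at 15.2 ± 7.36 CPM in control, and Kcne2 at 0.18, 5.69, 1.31 and 3.06 CPM against 0.347 ± 0.134 CPM. Of 9 choroid plexus genes, 0 fell, 3 rose and 6 did not pass the test. For choroid plexus, the count was 0 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.0732). The list was called higher against the 2 controls of the same sex (camera adjusted p = 0.0448, adjusted p = 0.505 with an estimated correlation). Kcne2 (2.82), Calml4 (1.72) (not called without control 4 or library 2 labelled Pax6 cKO, adjusted p = 0.0505 to 0.0575) and Ttr (3.32) (not called without control 2, 3 or 4, adjusted p = 0.0509 to 0.0645) rose. In the erythroid list of 10, 0 fell, 3 rose and 7 did not pass the test. For erythroid cells, the count was 2 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.349). Hbb-bs (0.89), Hbb-bt (0.70) and Tfrc (0.35) rose. Of 12 microglia genes, 0 fell, 3 rose and 9 did not pass the test. For microglia, the count was 0 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.349). Of 12 endothelial genes, 1 fell, 3 rose and 8 did not pass the test. For endothelial cells, the count was 1 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.807). Among 10 pericyte genes, 1 fell, 3 rose and 6 did not pass the test. For pericytes, the count was 3 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.807). For the 11 genes of meninges and fibroblasts, 2 fell, 1 rose and 8 did not pass the test. For meningeal genes, the count was 2 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.972). Dcn rose (0.72) (not called without control 2 or 3 or library 3 labelled Pax6 cKO, adjusted p = 0.0525 to 0.0583), and Fn1 (−0.94) and Cxcl12 (−0.32) fell. Median, mean and camera direction differed in sign for mitosis (median −0.02, mean −0.06, test higher), DNA replication (−0.04, −0.01, higher), oligodendrocyte precursors (−0.11, 0.02, higher), endothelial cells (−0.08, 0.05, higher), meninges (0.12, 0.06, lower) and erythroid cells (0.16, −0.02, higher).

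Without control replicate 3 the count of higher genes in the libraries labelled Pax6 cKO was 1732 and without control replicate 4 it was 1798. Besides the genes above, the calls of Kcne2, Calml4, Ttr, Hbb-bs, Hbb-bt, Tfrc, Dcn, Rbpj, Bcl11a, Smarca4, Fabp7, Stmn2, Crym and Insm1 were lost against the 2 controls of the same sex (adjusted p of 0.0642 to 0.38), and the controls (lane 8) shared no lane with the libraries labelled Pax6 cKO (lane 1).

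**Figure D3:**
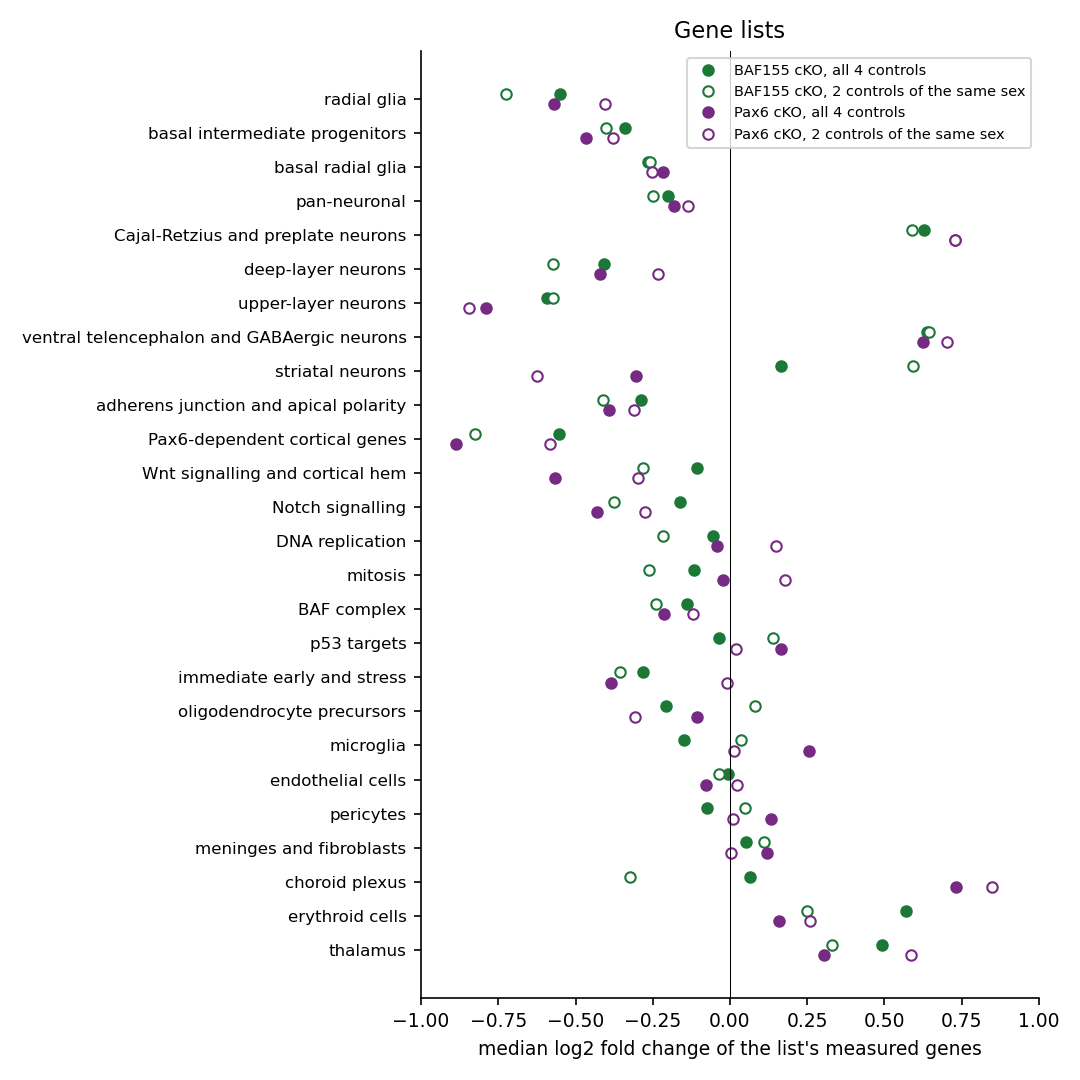
Median log2 fold change against control of the measured genes of each of the 26 lists, for the BAF155 cKO (green) and the libraries labelled Pax6 cKO (purple). Filled points use all 4 controls and open points the 2 controls of the same sex; the upper-layer list lies at −0.59 and −0.79 with all 4 controls.

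Many genes moved the same way in both cKOs. With the 4 controls, 704 genes were higher in both and 965 lower in both, and 8 were called in opposite directions. Independent lists of these sizes would share 166, 236 and 396 genes. The highest shared genes, by the smaller of both changes, were Arid3c, Prdm13, Paupar, Kirrel2 and Sim1, and the lowest Slc14a1, Rlbp1, Neurod4, Pdlim3 and Dmrta1. Against the 2 controls of the same sex Sim1 was not called in the libraries labelled Pax6 cKO (log2 fold change 1.91, adjusted p = 0.0805). Across the tested genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.629 and a covariance of 0.147. In 20 simulations of unchanged groups against the same controls the mean r was 0.503 (highest 0.523) and the mean covariance 0.0217 (highest 0.0233). In these simulations 0 genes were called in both. With each cKO set against its 2 controls of the same sex, no control was shared. Then 480 genes were higher in both, 767 lower in both and 0 opposite, with an r of 0.637 and a covariance of 0.147. Over the other 5 ways of dividing the controls between the cKOs, 109 to 154 genes were higher in both and 337 to 414 lower. These fits gave an r of 0.143 to 0.513 and a covariance of 0.0470 to 0.132. Without 1 library the shared counts moved by over 1.5 times for BAF155 cKO replicates 1 (368 higher), 2 (1271 higher, 1657 lower) and 4 (249 and 535), control replicates 1 (1604 lower), 3 (257 and 525) and 4 (317 and 571) and replicate 3 labelled Pax6 cKO (453 higher).

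**Figure D4:**
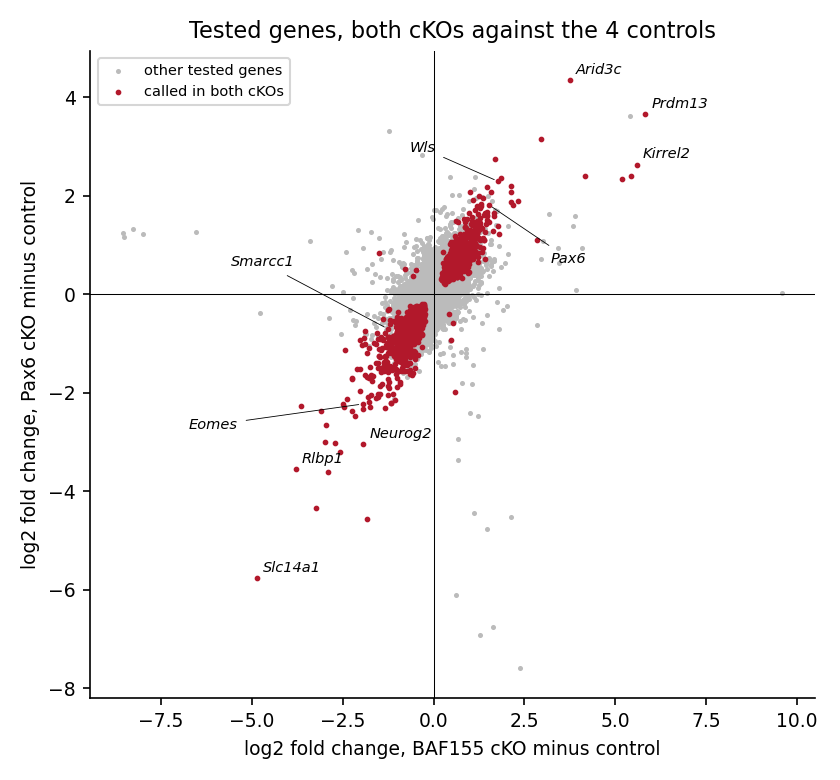
Log2 fold change against the 4 controls of each of the 16511 tested genes, in the BAF155 cKO (x axis) and in the libraries labelled Pax6 cKO (y axis). Red points are the genes called in both; Slc14a1 and Rlbp1 lie far below 0 and Prdm13, Kirrel2 and Arid3c far above 0 on both axes.

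Direct comparison of the cKOs tested where their effects differ. The BAF155 cKO was higher than the libraries labelled Pax6 cKO for 379 genes and lower for 332, of which 63 and 91 by at least 2-fold. The highest were Prss41 (3.71), Tagap (3.40), Sim1 (3.03), Kirrel2 (2.96) and Pla2g4b (2.88). With controls of the same sex Tagap had 0.44, Sim1 4.53, Kirrel2 2.99 and Pla2g4b 3.15, none of them called (adjusted p = 0.203 to 0.852). Lowest were Ttr (−4.56), the ribosomal protein gene Rpl29 (−4.47), Dsc3 (−3.28), Prss56 (−2.94) and Eif3j2 (−2.63). Neurog2 (1.10), Neurog1 (2.75) and Tfap2c (0.78) fell less in the BAF155 cKO, and Slc17a6 (0.80) too. The first 3 were 0.48, 1.42 and 0.27 and not called with controls of the same sex (adjusted p = 0.785, 0.75 and 0.802). All BAF155 cKO libraries carry Xist and all libraries labelled Pax6 cKO carry Y-linked transcripts, so sex and genotype cannot be told apart in this contrast. When each effect was taken against the 2 controls of the same sex, 6 genes were higher and 7 lower, of which 5 and 4 were also called directly. The calls of Prss41 (not called without BAF155 cKO 2 or library 2, 3 or 4 labelled Pax6 cKO, adjusted p = 0.0543 to 0.0821), Ttr (not called without BAF155 cKO 1, 2, 3 or 4 or library 2, 3 or 4 labelled Pax6 cKO, adjusted p = 0.0546 to 0.0942), Rpl29 (not called without BAF155 cKO 1, 2, 3 or 4 or library 1, 2, 3 or 4 labelled Pax6 cKO, adjusted p = 0.074 to 0.117), Eif3j2 (not called without BAF155 cKO 1, 2 or 4 or library 1, 2, 3 or 4 labelled Pax6 cKO, adjusted p = 0.0804 to 0.139), Neurog1 (not called without BAF155 cKO 2 or library 2 or 4 labelled Pax6 cKO, adjusted p = 0.0526 to 0.0724) and Tfap2c (not called without library 4 labelled Pax6 cKO, adjusted p = 0.057) were each lost without 1 library. Prss41 and Rpl29 were also among 7 autosomal genes that part the libraries along the same line as sex. Sex and a difference in the background of the animals cannot be told apart there. The differences of Prss41 and Rpl29 had the opposite sign with controls of the same sex (−0.30 and 0.13). Of the genes named, Smarcc1 (−1.09), Calb2 (−0.69) and Slc17a6 (0.74) were among the 13 called with controls of the same sex. Leaving out any library labelled Pax6 cKO or BAF155 cKO replicate 2 moved both counts by over 1.5 times (143 to 203 without a library labelled Pax6 cKO, 216 higher and 202 lower without BAF155 cKO replicate 2), and without BAF155 cKO replicate 1 or 3 the lower count was 177 or 203.

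Among the 26 lists, 7 were called in the direct contrast. Genes of basal intermediate progenitors (7 higher and 2 lower of 22, 9 and 2 adjusted over the list alone), adherens junctions (5 higher and 0 lower of 35, 6 and 2 adjusted over the list alone), Pax6-dependent cortical genes (4 higher and 0 lower of 12, 6 and 1 adjusted over the list alone), Wnt signalling (3 higher and 1 lower of 26, 9 and 2 adjusted over the list alone) and Notch signalling (2 higher and 0 lower of 17, 6 and 0 adjusted over the list alone) were higher in the BAF155 cKO. Lists of microglia (0 higher and 1 lower of 12, 0 and 3 adjusted over the list alone) and choroid plexus (0 higher and 3 lower of 9, 0 and 5 adjusted over the list alone) were lower. Camera adjusted p was 3.43e-05, 0.000773, 0.000979, 0.00324, 0.000979, 0.000979 and 0.00324 in this order, and adjusted p = 0.712 with an estimated correlation for each. The other 19 lists had a camera adjusted p of 0.0701 to 0.862. Their counts were 2 higher and 4 lower of 22, 3 and 5 adjusted over the list alone for radial glia, 3 higher and 1 lower of 16, 4 and 2 adjusted over the list alone for basal radial glia, 0 higher and 1 lower of 18, 4 and 3 adjusted over the list alone for pan-neuronal genes, 2 higher and 2 lower of 12, 2 and 3 adjusted over the list alone for Cajal-Retzius and preplate neurons, 1 higher and 1 lower of 14, 1 and 1 adjusted over the list alone for deep-layer neurons and 3 higher and 0 lower of 14, 3 and 1 adjusted over the list alone for upper-layer neurons. For the ventral telencephalon the count was 0 higher and 3 lower of 24, 0 and 5 adjusted over the list alone, for DNA replication 0 higher and 2 lower of 24, 0 and 2 adjusted over the list alone, for immediate early and stress genes 1 higher and 1 lower of 14, 1 and 1 adjusted over the list alone, for oligodendrocyte precursors 1 higher and 0 lower of 8, 1 and 2 adjusted over the list alone, for endothelial cells 0 higher and 1 lower of 12, 0 and 1 adjusted over the list alone and for pericytes 1 higher and 0 lower of 10, 1 and 4 adjusted over the list alone. It was 1 higher and 1 lower of 11, 1 and 1 adjusted over the list alone for meninges, 2 higher and 0 lower of 10, 3 and 0 adjusted over the list alone for erythroid cells and 1 higher and 0 lower of 8, 1 and 0 adjusted over the list alone for the thalamus, and no gene of the striatal, mitosis, BAF complex and p53 lists was called. Median, mean and camera direction differed in sign for radial glia (median 0.13, mean 0.05, test lower) and meninges (−0.14, 0.01, lower). Camera called 11 lists with controls of the same sex, and of the 7 above only the choroid plexus list was among them. The median log2 difference of the 5 lists that were higher turned negative there (−0.087, −0.13, −0.076, −0.015 and −0.17 in the order above). Smallest in camera adjusted p among the 11 were mitosis (2.65e-13, median −0.44), DNA replication (1.87e-09, −0.39) and deep-layer neurons (4.19e-05, −0.30). These 3 lists were lower in the BAF155 cKO, with 0 of their genes called. None of the 11 was called with an estimated correlation (lowest adjusted p = 0.378) or by fry (0.337).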

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

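Counting other splits of the libraries and dividing the controls between the cKOs were planned before the data were examined, but the bound that decides each test below was written only after its result was seen. The tests on exchanged labels, on reads outside the deletion, on the sex of the embryos, on GC content and length and on lane were chosen only after the result was seen.

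Chance as the reason for the number of called genes was tested by fitting each of the 35 ways to part 8 libraries into 4 and 4. For the BAF155 cKO against control 1 of the 35 splits, the real one, gave as many calls, with 1035 genes against 609 in the highest other, which set BAF155 cKO replicates 1, 3 and 4 with control replicate 1 against the rest. For the libraries labelled Pax6 cKO against control it was 1 of 35, with 6543 genes against 0. For the direct contrast it was 1 of 35, with 996 genes against 330 in the split of BAF155 cKO replicates 1 and 4 with replicates 1 and 3 labelled Pax6 cKO against the rest. In each of these 3 comparisons the real split gave the most calls, the strongest result that 35 splits allow. This argues against chance but does not exclude it, since the bound was written after the result. Libraries of a group may also be technical, in which case the splits do not test chance between embryos. For control this cannot hold for all 4, since replicates 1 and 2 differed in sex from 3 and 4. The test says nothing about sex or lane.

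Pax6 counts were higher, not lower, in the libraries labelled Pax6 cKO. If control and Pax6 cKO labels had been exchanged, the list of Pax6-dependent cortical genes would rise in these libraries, but its median log2 fold change was −0.89. If BAF155 cKO and Pax6 cKO labels had been exchanged, Smarcc1 would be higher in the libraries labelled BAF155 cKO, but its log2 fold change between them was −0.55 (adjusted p = 0.0286, and 0.0536 to 0.0852 on leaving out BAF155 cKO replicate 1 or 4 or any 1 library labelled Pax6 cKO) and −1.09 with controls of the same sex. Reads from parts of the gene outside the deletion, with its transcription unchanged, are argued against as the whole reason, since the control libraries hold these reads too and the log2 fold change against them was 1.82 (SE 0.12). Such reads could explain why the counts did not fall, which whole-gene counts cannot show. Counts of Pax6 transcript, intact or not, were thus higher in these libraries, though lane and group cannot be told apart. Whether the transcript was intact, and why its counts were higher, stays open and was not tested.

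The control libraries fell into the pairs 1, 2 and 3, 4, with 41 genes higher and 69 lower in replicates 3 and 4, of which 37 and 64 were autosomal. Bias by GC content or gene length as the whole reason is argued against, since 108 genes were called after the correction and 110 before. An autosomal set of 7 genes, Atp6v0c-ps2, Gm11868, Gm15610, Gm6916, Gm9825, Prss41 and Rpl29, named after their values were seen, parted the BAF155 cKO and these 2 controls from the other 6 libraries by at least 4-fold, against 0 genes for each of the other 5 choices of 2 controls. Sex and this pairing coincide in all 12 libraries, so the sex of the embryos alone and a difference in the background of the animals cannot be told apart. Shares of reads followed the same pairs: mitochondrial genes held 2.27% and 2.18% of reads in control replicates 1 and 2 and 1.21% and 1.38% in 3 and 4, ribosomal protein genes 1.14% and 1.09% against 0.865% and 0.819%, and the 10 most abundant genes 3.71% and 3.63% against 2.91% and 2.94%. A difference in the handling of the tissue between the pairs was not tested and stays open.

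The log2 fold changes of both cKOs correlated across genes (covariance 0.147). Shared control libraries as the whole reason are argued against, since the covariance was above 0 for each of the 6 ways of dividing the controls between the cKOs (lowest 0.0470). GC content or gene length as the whole reason is argued against as well, with a covariance of 0.125 after the correction. Lane or batch of the control libraries may contribute and stays open: 10 genes were called between the lanes of the BAF155 cKO libraries by edgeR (840 at an unadjusted p under 0.05, 0 by voom on these 4 libraries), but no cKO library lies in lane 8 of the controls. A change common to both cKOs, which the design would allow, stays open too.

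In 15 of 354 groups of 4 libraries (4.24%), 1 library stood far from the other 3, a gap that chance gives in about 1 in 20 groups. Total counts were 30.31 M in control replicate 1 and 21.4 to 21.8 M in the other controls. The 10 most abundant genes held 3.901% of reads in replicate 2 labelled Pax6 cKO and 4.20% to 4.22% in the others. In the BAF155 cKO, Alb was at 156.5 CPM in replicate 4 (0.621 to 25.9 in the others), Ctnnd2 at 91.8 CPM in replicate 4 (129 to 136), Eif3j2 at 4.313 CPM in replicate 3 (0.194 to 0.255), and in replicate 2 Kirrel2 was at 20.34 CPM (11.9 to 12.6), Notch3 at 38.87 CPM (32.6 to 33.7) and Plk1 at 31.84 CPM (21.9 to 23.0). In control, Sdc3 was at 280.9 CPM in replicate 2 (331 to 338), and in replicate 1 Crym was at 73.54 CPM (33.3 to 38.5) and Tfrc at 132.2 CPM (121 to 123). In the libraries labelled Pax6 cKO, Frmd7 was at 3.688 CPM in replicate 3 (3.01 to 3.13), Smarca4 at 411.8 CPM in replicate 2 (348.5 to 358), and in replicate 4 Dlx1 was at 627.3 CPM (666 to 673) and Calb2 at 63.14 CPM (68.4 to 68.8).

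Effects of the cKOs differed by the direct contrast for 49 of the 113 genes named, some of them chosen by this contrast. Of all tested genes it called 4.31%. The higher share among the genes named follows from how they were chosen and shows nothing about them. Of the 49, 27 were higher and 22 lower in the BAF155 cKO, and 29 were called the same way in both cKOs. With controls of the same sex, Smarcc1, Slc17a6 and Calb2 were called, and the difference had the opposite sign for Uncx (−0.69), Prss41 (−0.30), Rpl29 (0.13) and Tbr1 (−0.055). Other differences shrank there, such as those of Lhx9 (0.0072), Prdm13 (0.67), Notch3 (0.21) and Celsr1 (0.50). Some grew, such as those of Sim1 (4.53) and Nphs1 (4.63), also without a call. The values below are those without this change of controls. Among progenitor and neuron genes the log2 difference, BAF155 cKO minus the libraries labelled Pax6 cKO, was 1.10 for Neurod4, 2.75 for Neurog1, 1.10 for Neurog2, 0.78 for Tfap2c, 0.63 for Veph1, 1.30 for Foxn4, 0.40 for Sdc3, 0.51 for Ebf3, 0.56 for Unc5d, 0.80 for Slc17a6, 0.70 for Tbr1 and 0.85 for Lhx9. It was −1.39 for Tac2, −0.53 for Aldoc, −0.59 for Calb2, −1.37 for Crym, −0.39 for Dlx1 and −0.69 for Dlx6os1. For genes of junctions and signalling it was 0.95 for Cdh4, 1.07 for Celsr1, 0.53 for Wnt5a, 0.75 for Sfrp2, 0.59 for Notch2, 0.64 for Notch3, −0.55 for Dkk3 and −0.52 for Wls. Ranked genes gave 2.18 for Prdm13, 2.96 for Kirrel2, 3.03 for Sim1, 2.83 for Nphs1, 2.31 for Uncx, 3.71 for Prss41, 3.40 for Tagap, 2.88 for Pla2g4b, −2.38 for Ltbp2, −1.06 for Nmbr, −1.08 for Synpr, −1.52 for Serpinb2 and −1.33 for Frmd7. The lowest gave −4.47 for Rpl29, −3.28 for Dsc3, −2.94 for Prss56 and −2.63 for Eif3j2. The rest were Smarcc1 (−0.55), Btg1 (−0.44), Cxcl12 (−0.94), Fn1 (0.90), Ttr (−4.56) and Kcne2 (−3.14). Leaving out 1 library, of either cKO, ended 19 of these calls, those of Btg1, Dkk3, Dlx1, Dlx6os1, Eif3j2, Foxn4, Kcne2, Lhx9, Neurog1, Prss41, Rpl29, Sdc3, Serpinb2, Smarcc1, Tac2, Tbr1, Tfap2c, Ttr and Wls, with adjusted p of 0.0505 to 0.139.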

How the results depend on the processing

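Controls of the same or the other sex, and replicates 1 and 3 labelled Pax6 cKO alone, were alternatives chosen after seeing the data. The others were planned, and for the counts and list tests not named below an alternative stayed within 1.5 times the reported value. With controls of the same sex, 2085 genes were higher and 2449 lower in the BAF155 cKO, 744 and 1028 in the libraries labelled Pax6 cKO and 6 and 7 in the direct contrast, where camera called 11 lists at the preset correlation and 0 with an estimated one, and fry 0. With the GC and length correction added these counts were 1608 and 2075, 550 and 690, and 6 and 14, with 290 genes higher and 500 lower in both cKOs and an r of 0.596. With controls of the other sex, 343 genes were higher and 680 lower in the BAF155 cKO and 3433 and 3707 in the libraries labelled Pax6 cKO. In both cKOs 152 were higher and 375 lower, with an r of 0.143. With replicates 1 and 3 labelled Pax6 cKO alone, 1236 genes were higher and 1718 lower, 36 and 35 in the direct contrast and 387 and 651 in both, with an r of 0.558. Fewer control or cKO libraries stand behind each effect here. For the calls against control, the number of control libraries alone does not account for the changes. Against control replicates 3 and 4, 4534 genes were called in the BAF155 cKO and 7140 in the libraries labelled Pax6 cKO. Against control replicates 1 and 2, also 2 libraries, these counts were 1023 and 1772. For the direct contrast, and for replicates 1 and 3 labelled Pax6 cKO alone, these values do not show whether fewer libraries account for the lower counts. The cause was not tested further.

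By DESeq2 the direct contrast called 724 genes higher and 608 lower, with an r of 0.516. Without a filter r was 0.519. In a fit of only the 8 libraries compared, 379 genes were higher and 656 lower in the BAF155 cKO. A fold threshold of 1.2, which asks for more than a change from 0, left 213 and 451 in the BAF155 cKO, 859 and 1052 in the libraries labelled Pax6 cKO, 94 and 82 in the direct contrast and 123 and 317 in both. BAF155 cKO replicates 1 and 2 alone (lane 1) gave 258 and 424 against control, 164 lower in the direct contrast, 182 and 347 in both and an r of 0.560. BAF155 cKO replicates 3 and 4 alone (lane 3) gave 142 and 67 in the direct contrast and an r of 0.529. With an estimated correlation, camera called 2 lists in the BAF155 cKO, 0 in the libraries labelled Pax6 cKO and 0 in the direct contrast, where fry called 0 too. These counts were 0, 2 and 0 with controls of the same sex as well. At the preset correlation camera called 12, 12 and 7, and fry called 11, 14 and 0, with all 4 controls.

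The replicate numbers did not pair the samples across all groups: of 12 correlations between libraries of the same number across groups 4 lay above 0.1. For 2 of the 12 the own number correlated best. These were replicates 1 (0.377) and 2 (0.323) of the BAF155 cKO with those labelled Pax6 cKO, all in lane 1. As a replicate block the numbers gave 250 genes higher in the direct contrast, and together with the GC and length correction 234 higher and an r of 0.577. The cause was not tested.

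Leaving out 1 library at a time, the count ranged from 346 to 1973 higher and 655 to 2100 lower in the BAF155 cKO, from 1732 to 2908 higher and 2093 to 3693 lower in the libraries labelled Pax6 cKO and from 158 to 419 higher and 143 to 367 lower in the direct contrast. In both cKOs it ranged from 249 to 1271 higher and 525 to 1657 lower, with an r of 0.591 to 0.687. Lists called ranged from 11 to 14, 11 to 13 and 7 to 10 for the BAF155 cKO, the libraries labelled Pax6 cKO and the direct contrast.

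For the genes that the rule names, including those not in this text, 3187 values over the alternatives kept side and direction in the BAF155 cKO. There 186 lost the call, 124 gained it and 98 changed sign without being called in either fit. In the libraries labelled Pax6 cKO these counts were 3042, 309, 45 and 31, and in the direct contrast 1350, 516, 0 and 50. The direct contrast was followed for the genes that the rule names there, the targeted and fixed genes and the genes of this text that it calls. Where a gene was called in the reported fit or in the alternative, the sign turned as follows. The sign turned with controls of the same sex, without and with the GC and length correction, for Prss41 in the libraries labelled Pax6 cKO (0.57 and 0.50) and in the direct contrast (−0.30 and −0.32), and in the direct contrast for Uncx (−0.69 and −0.56), Rpl29 (0.13 and 0.18), Tbr1 (−0.055 and −0.044) and Hbb-y (−0.043 and −0.18). With both changes together it turned for Cspg4 (0.0041) and Gins1 (−0.39, called at adjusted p = 0.0332) in the BAF155 cKO and for Fabp7 (−0.027) and Hopx (−0.034) in the libraries labelled Pax6 cKO. There Plxnd1 turned with the GC and length correction (0.045), also with the replicate block (0.041) or with controls of the same sex (0.044), and Gins1 with the correction (−0.0059) and with the replicate block added (−0.0025). The cause was not tested. At 15.2 to 32.05 M reads per library, the filter on low counts left 16511 of 48709 genes to test.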

Other observations

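The gene families and genes in this part were chosen after the data had been seen. Of 1369 long noncoding RNA genes, 168 were higher and 34 lower in the BAF155 cKO and 232 and 60 in the libraries labelled Pax6 cKO, against 745 and 1180, and 2382 and 2999, of 14079 protein-coding genes. With controls of the same sex the counts for long noncoding RNA genes were 266 and 37, and 75 and 25, against 1660 and 2372, and 645 and 985, of protein-coding genes. The share higher in the libraries labelled Pax6 cKO was then 5.48% of long noncoding RNA genes and 4.58% of protein-coding genes. Of 53 genes of the protocadherin clusters, which encode adhesion proteins of neurons, 8 were higher and 3 lower in the BAF155 cKO and 1 and 14 in the libraries labelled Pax6 cKO, or 8 and 4, and 0 and 5 with controls of the same sex. Of 22 core histone genes, 4 were higher and 0 lower in the BAF155 cKO and 8 and 1 in the libraries labelled Pax6 cKO, or 3 and 2, and 5 and 0 with controls of the same sex.

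Ribosomal protein genes depended on the controls used. Of 76, 1 was higher in the BAF155 cKO and 51 in the libraries labelled Pax6 cKO with all 4 controls, and 47 and 3 with controls of the same sex, with 0 lower in each case. Of 21 mitochondrially encoded genes, 1 and 8 were higher with all 4 controls and 14 and 0 with controls of the same sex.

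With controls of the same sex the effects of the cKOs differed for 13 genes. Besides those named before, Pdgfra, a receptor gene of oligodendrocyte precursors, had a log2 fold change of 0.95 in the BAF155 cKO and −0.17 in the libraries labelled Pax6 cKO, a difference of 1.12 (adjusted p = 0.0193). The difference was −1.41 for Lpar1, a receptor of lysophosphatidic acid, 0.92 for Sorl1, 0.87 for the phosphatase gene Ptprt, 1.01 for the cadherin gene Cdh12, −1.92 for Ahcy and 2.62 for Eif3j1. It was −1.65 for 2900097C17Rik, −1.31 for Pcna-ps2 and −1.22 for 9630028B13Rik. For Eif3j2, the paralog of Eif3j1, it was −2.62 (adjusted p = 0.762), and reads of these paralogs are hard to assign.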
